A study of Mus musculus with 14 samples.

How the data were processed

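RNA from tumours of 4T1 cells, a mouse mammary carcinoma line, was sequenced in 14 libraries: 4 from animals given saline (PBS), 5 from animals given cyclophosphamide at 100 mg/kg (CTX100) and 5 at 140 mg/kg (CTX140). Groups were taken from the sample labels. The deposited count table holds whole-number read counts per Ensembl gene, 1 column per library, which the authors did not normalise. The genome build mm10 and DESeq2 are named per the submitters' processing notes, with no role given for the tool. The aligner, the counting tool and the strand setting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. The deposited FPKM table was made by the authors from the same counts: every value that was not 0 equalled the count divided by the listed gene length and by 1 constant per library. That constant equalled the DESeq2 size factor multiplied by the geometric mean of the library totals, so these FPKM values refer to a scaled library size.

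The count table lists 54532 genes, of which 54409 have an identifier in GENCODE release M21 and 53499 of these the same coordinates. Coordinates are those of the deposited table, on mm10. Symbols were taken from the same table; 100 of them belong to more than 1 identifier. No library was left out. Library totals, in units of 1000000 counts, were 15.2 to 17.1 in PBS, 15.9 to 19.3 in CTX100 and 14.4 to 18.8 in CTX140. Counting intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

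Counts were tested per gene with edgeR 4.0.16 under R 4.3.3: TMM factors, the filterByExpr filter by group, which left 15360 genes, and the robust quasi-likelihood test, two-sided, with Benjamini-Hochberg adjustment over all genes tested in a contrast. All 14 libraries entered 1 fit with a mean per group and no covariate. The contrasts were CTX100 against PBS, CTX140 against PBS, CTX140 against CTX100, and the mean of both doses against PBS. A gene was called at an adjusted p under 0.05. Values per library are CPM, counts per 1000000 of the TMM-scaled library size. A log2 fold change is the fitted one, with its standard error (SE). For a gene with 0 counts in every PBS library, the fold is a lower bound against a floor of 3 counts over the group. For 1 to 3 counts in PBS, the ratio is given with its exact 95% counting interval.

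There were 24 lists of cell type markers and 20 lists of process genes, 614 symbols in all, of which 2 are not in the table. The 40 lists with at least 4 tested members were tested with camera in limma 3.58.1, with a preset correlation of 0.01 between genes and adjustment over the lists. Camera asks whether a list moved relative to the other genes. Its calls were checked with an estimated correlation and with fry, which asks whether a list's genes moved 1 way without comparing them with other genes. The level of a list in a library is the mean over its tested members of log2 CPM, with a prior count of 2. Levels were compared between groups by a two-sided exact permutation test, adjusted over the 40 lists; the smallest p it can give is 0.00794 for a pair of groups and 0.000999 for both doses against PBS. No tested member of any list had 0 counts in every library of a compared group.

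Genes are named by a rule. For each comparison with PBS it takes the 8 highest and 8 lowest fold changes among called protein-coding genes with a mean of at least 1 CPM over the compared groups and a symbol that is not a model name; for CTX140 against CTX100 it takes 5 and 5. It then takes up to 2 called members with the smallest p from each list, going through the lists by smallest camera p up to 16 genes. The tests, contrasts, lists and this rule were set before the data were examined; genes named outside the rule are said to be so. Some genes taken by the rule are not reported here.

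The per-gene test was checked on simulated counts in which 200 genes, 50 per fold size, had been changed by known folds. In the simulation of CTX100 against PBS (15187 genes) it recovered 20, 46, 80 and 80% of the genes changed 1.5-, 2-, 3- and 4-fold, with 7 false calls among 120. For CTX140 against PBS (15154 genes) these shares were 14, 54, 88 and 94%, with 2 false calls among 127. For CTX140 against CTX100 (15174 genes) they were 22, 62, 82 and 96%, with 7 false calls among 138. For both doses against PBS (15162 genes) they were 26, 66, 76 and 94%, with 11 false calls among 142. No recovered gene had the wrong direction. Of simulated lists, camera called 10 of 10 shifted ones and 0 of 30 others, and the permutation test of levels did the same. The simulated genes varied independently of one another, so this check does not cover false calls among genes that vary together. In other splits of the real libraries, camera called a median of 13 to 16 of the 40 lists, depending on the contrast.

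The alternatives were a fold threshold, RLE and upper quartile factors, no filter and a stricter filter of 1 CPM in 4 libraries, lists of tissue that may surround a tumour left out, the replicate number as a block, only the groups compared, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1), and leaving out each library in turn. After the data had been seen, the fibroblast level as a covariate and the joint omission of 3 libraries with high B cell levels were added. Overlap between the doses was set against 30 simulations of unchanged groups. In these all 14 libraries were simulated, PBS included, and both doses were compared with the same simulated PBS libraries. It was also set against fits in which a different pair of the real PBS libraries served each dose. Other splits of the libraries were refitted, 100 per contrast. Figures were drawn with matplotlib 3.10.9.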

Results

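Bulk RNA-seq was made from subcutaneous 4T1 mammary carcinomas in mice, with 4 PBS, 5 CTX100 and 5 CTX140 libraries. Cyclophosphamide (CTX) is an alkylating cytotoxic drug that crosslinks DNA. Per the labels, 1000000 cells were injected in the mammary area, injections of PBS or of 100 or 140 mg/kg CTX began on day 9 at a tumour volume of about 100 mm3 and were given every 6 days for 3 cycles, and tumours were taken on day 3 after the third cycle. The labels do not say that each library is a separate mouse, so p-values measure the spread between these samples. Totals ran from 14.4 to 19.3 (in units of 1000000 counts). The first principal component held 37.8% of the variance and placed CTX100 between the other groups, with mean scores of -40.9 in PBS, -9.38 in CTX100 and 42.1 in CTX140. Mitochondrially encoded transcripts took 4.72 ± 1.02% of counts in PBS (SD, n = 4), 4.53 ± 1.52% in CTX100 (n = 5) and 6.02 ± 2.23% in CTX140 (n = 5), a difference within the spread between libraries.

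The comparison of CTX100 with PBS asks what the lower dose changed in the tumour. Interferon-induced and inflammatory genes rose, together with p53 targets, genes of cell division and fibroblast markers, while 5 of 16 genes of cholesterol synthesis were called lower. Of 15360 genes tested, 245 were called, 184 higher and 61 lower. Mx1, an antiviral GTPase induced by type I interferon (ENSMUSG00000000386, chromosome 16, 97447035 to 97462907, mm10), rose from 9.03 ± 3.21 CPM in PBS (SD, n = 4) to 22.3 ± 1.74 CPM in CTX100 (n = 5), a log2 fold change of 1.30 ± 0.21 (SE) with an edgeR adjusted p of 0.0134. Its lowest CTX100 library, at 20.2 CPM, lay above its highest PBS library, at 13.1 CPM. Ifit3, which may share reads with its near-copy Ifit3b, rose by 1.20 ± 0.20 on the log2 scale (adjusted p = 0.0164). The type I interferon list had 10 of 21 members called higher (19 when adjusted over the list alone) and none lower. Its level rose by 0.94, from 5.60 ± 0.32 in PBS (n = 4) to 6.54 ± 0.19 in CTX100 (n = 5) (exact permutation adjusted p = 0.0289).

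Cytokine genes rose with the interferon response. Il1b, which encodes a cytokine of myeloid cells, went from 82.3 ± 19.4 to 276 ± 119 CPM, a log2 fold change of 1.75 ± 0.28 (adjusted p = 0.0152); reads of its antisense neighbour cannot be separated from it. The neutrophil attractant Cxcl3 rose by 1.73 ± 0.32 (adjusted p = 0.0228). The T cell attractants Cxcl10 and Cxcl11 rose by 1.17 ± 0.22 (adjusted p = 0.0218) and 1.70 ± 0.34 (adjusted p = 0.0270). The inflammatory list had 9 of 23 members called higher (17 adjusted over the list alone), with a level 1.17 higher (exact permutation adjusted p = 0.0289). Of the interferon gamma list, 4 of 17 were called higher (10 adjusted over the list alone), and its level rose by 0.58 (exact permutation adjusted p = 0.0289).

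Among the genes that the naming rule could take, Reg3g, which encodes an antimicrobial lectin, and Reg1, of the same gene family, had the highest fold changes. Reg3g was read with 415 counts in CTX100 and 2 in PBS, a ratio of 156 (95% counting interval 42.9 to 1292), and Reg1 rose by 4.38 ± 0.72 (adjusted p = 0.0164); either may share reads with other genes of its family. Stromal genes also rose. Among them Clec3b, Efemp1, Fndc1, Dpt, Abi3bp and Fbn1, which encode matrix and fibroblast proteins, had log2 fold changes of 3.96 ± 0.89, 3.31 ± 0.56, 2.76 ± 0.61, 2.73 ± 0.55, 2.57 ± 0.35 and 1.66 ± 0.35. The mast cell tryptase Tpsab1, a near-copy of Tpsb2, rose by 2.57 ± 0.54 (adjusted p = 0.0329). The fibroblast list had 3 of 14 members called higher (10 adjusted over the list alone) and a level 1.11 higher (exact permutation adjusted p = 0.0289). The mast cell list had 1 of 7 called (6 adjusted over the list alone) and a level 1.78 higher (exact permutation adjusted p = 0.0488).

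Cell division genes were higher at CTX100. Ccnb2 and Bub1b, which act in mitosis, rose by 0.59 ± 0.12 (adjusted p = 0.0246) and 0.64 ± 0.13 (adjusted p = 0.0268), and Rrm2 and Lig1, which act in DNA synthesis, by 0.67 ± 0.16 (adjusted p = 0.0431) and 0.44 ± 0.10 (adjusted p = 0.0450). The mitosis list had 6 of 21 members called higher (18 adjusted over the list alone) and its level rose by 0.50, and the DNA replication list had 2 of 21 (13) and rose by 0.38 (exact permutation adjusted p = 0.0289 for each). The p53 target list had 4 of 20 called higher (5 adjusted over the list alone) and rose by 0.46, from 3.90 ± 0.07 to 4.35 ± 0.09 (exact permutation adjusted p = 0.0289). The list of crosslink and recombination repair had 1 of 18 called (9 higher and 1 lower adjusted over the list alone) and rose by 0.34 (exact permutation adjusted p = 0.0289).

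Among lower genes, Spp1, which encodes the secreted phosphoprotein osteopontin, went from 6465 ± 3131 to 2952 ± 278 CPM, a log2 fold change of -1.13 ± 0.23 (adjusted p = 0.0244). Itga8, an integrin subunit, and its ligand Npnt fell by 1.91 ± 0.34 and 1.25 ± 0.23 on the log2 scale. Bmp7, Piezo2, Fgf1, Tmem231 and Adamtsl3 had log2 fold changes of -1.26, -1.26, -1.24, -1.14 and -0.97. Cyp51, which encodes an enzyme of cholesterol synthesis, fell by 0.88 ± 0.18 (adjusted p = 0.0271). The cholesterol list had 5 of 16 members called lower (10 adjusted over the list alone) and was called by camera (adjusted p = 1.35e-09, but 0.216 with an estimated correlation), while its level difference of -0.55 did not pass the permutation test (exact permutation adjusted p = 0.0595).

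Camera called 16 of the 40 lists, 14 higher and 2 lower, and the permutation test of levels called 13. The lists so called and not given above were adipocytes (level 1.47 higher, 0 of 10 members called), carcinoma epithelium (0.63 higher, 0 of 13) and red blood cells (a difference of -2.75, 0 of 6; 4 lower adjusted over the list alone), each with an exact permutation adjusted p of 0.0289, and the list of unfolded protein and amino acid stress (0.31 higher, 0 of 16; exact permutation adjusted p = 0.0488). Camera alone also called immature neutrophils (adjusted p = 0.00941), skeletal muscle (adjusted p = 0.0374) and matrix (adjusted p = 9.03e-06), whose levels did not pass (adjusted p = 0.440, 0.531 and 0.389 with an estimated correlation). On log2(FPKM + 1) the adipocyte level lost its call (exact permutation adjusted p = 0.0794), and camera lost skeletal muscle without PBS 1, PBS 3, CTX100 3 or CTX100 4 (highest adjusted p = 0.133). T cells differed by 0.02 (exact permutation adjusted p = 0.944), cytotoxic cells by 0.10 (0.847) and macrophages by -0.33 (0.420), none past the threshold. The median, mean and test of a list differed in sign in 4 lists. With an estimated correlation camera called none of the 40 (smallest adjusted p = 0.145 with an estimated correlation; raw p under 0.05 in 9 lists), and fry called 10.

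The number of genes called at CTX100 moved with single libraries and with the method, and 26 of the 29 entries taken by the naming rule lost their call without some library. The number was 280 without PBS 1, 686 without PBS 2, 17 without PBS 3, 28 without PBS 4, and 97, 78, 50, 69 and 51 without CTX100 1 to 5; it was 847 with DESeq2, 529 with only these groups fitted, 155 with limma on log2(FPKM + 1), 117 at a log2 change of at least 1, and 20 with the fibroblast level as a covariate.

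The comparison of CTX140 with PBS asks the same of the higher dose. Interferon, inflammatory, p53 and fibroblast genes rose and cholesterol genes fell, and adipocyte, granulocyte precursor and complement genes were higher than in PBS. Of 15360 genes, 3268 were called, 1711 higher and 1557 lower; the higher ones had a median log2 fold change of 1.38 and the lower ones of -0.58. Mx1 reached 36.8 ± 7.06 CPM in CTX140 (SD, n = 5) against 9.03 ± 3.21 CPM in PBS (n = 4), a log2 fold change of 2.02 ± 0.21 (adjusted p = 4.01e-05), and Ifit3 rose by 2.04 ± 0.21 (adjusted p = 4.01e-05). The type I interferon list had 20 of 21 members called higher (21 adjusted over the list alone). Its level was 7.03 ± 0.28 against 5.60 ± 0.32, a difference of 1.43 (exact permutation adjusted p = 0.0244).

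Ccl4, a chemokine gene of macrophages and lymphocytes, rose from 11.6 ± 2.40 to 58.1 ± 16.3 CPM, a log2 fold change of 2.33 ± 0.24 (adjusted p = 4.11e-05), and the cytokine gene Il1a rose by 2.18 ± 0.28 (adjusted p = 0.000165). The inflammatory list had 18 of 23 members called higher (18 adjusted over the list alone) and a level 1.68 higher (exact permutation adjusted p = 0.0244). Ido1 and Cxcl10, both induced by interferon gamma, rose by 1.91 ± 0.27 (adjusted p = 0.000329) and 1.56 ± 0.22 (adjusted p = 0.000371). That list had 12 of 17 called higher (15 adjusted over the list alone) and a level 0.89 higher (exact permutation adjusted p = 0.0244). The list of class I antigen presentation had 3 of 14 members called higher (4 higher and 1 lower adjusted over the list alone) and its level difference of 0.20 did not pass (exact permutation adjusted p = 0.121).

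The p53 targets rose further. Fas, a death receptor gene (chromosome 19, 34290659 to 34327770, mm10), went from 9.14 ± 1.11 to 23.8 ± 2.76 CPM, a log2 fold change of 1.38 ± 0.14 (adjusted p = 4.11e-05), and every CTX140 library (lowest 21.2 CPM) lay above every PBS library (highest 10.2 CPM). Eda2r, also a receptor gene under p53, rose from 0.0576 ± 0.0666 to 3.20 ± 1.39 CPM (log2 fold change 5.53 ± 0.61). The p53 list had 13 of 20 members called higher and 1 lower (15 and 1 adjusted over the list alone), and its level rose by 0.90 (exact permutation adjusted p = 0.0244). The mitosis list had 0 of 21 members called higher and 1 lower by edgeR (none adjusted over the list alone), and its level difference of 0.07 did not pass (exact permutation adjusted p = 0.732).

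Cholesterol synthesis showed the most uniform decrease. Insig1, a gene that follows the cell's sterol supply (chromosome 5, 28071363 to 28078662, mm10), went from 45.0 ± 5.70 to 14.7 ± 1.77 CPM, a log2 fold change of -1.61 ± 0.17 (adjusted p = 4.84e-05). Cyp51 fell by 1.68 ± 0.19 on the log2 scale (adjusted p = 6.48e-05) and Idi1 by 1.91 ± 0.27. The list had 14 of 16 members called lower (15 adjusted over the list alone) and none higher. Its level went from 5.16 ± 0.25 to 4.02 ± 0.16, a difference of -1.14 (exact permutation adjusted p = 0.0244).

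Stromal genes rose. Col3a1, a fibrillar collagen gene, went from 280 ± 76.0 to 1634 ± 717 CPM, a log2 fold change of 2.55 ± 0.32 (adjusted p = 0.000216). Mfap5, Lox, Fbn1 and Clec3b, all of matrix or fibroblasts, had log2 fold changes of 1.88 ± 0.24, 2.07 ± 0.28, 2.64 ± 0.36 and 6.07 ± 0.91. The fibroblast list had 13 of 14 members called higher (13 adjusted over the list alone) and a level of 6.57 ± 0.55 against 4.34 ± 0.25 (exact permutation adjusted p = 0.0244), and the matrix list had 13 of 27 called higher and 1 lower (19 and 2 adjusted over the list alone) and a level 0.89 higher (exact permutation adjusted p = 0.0373). The adipocyte genes Adipoq and Plin4 rose by 4.46 ± 0.71 and 3.25 ± 0.57; 8 of 10 members of that list were called (8 adjusted over the list alone) and its level was 3.04 higher (exact permutation adjusted p = 0.0244). Mast cell genes had 6 of 7 called (6 adjusted over the list alone) and a level 2.45 higher (exact permutation adjusted p = 0.0373), granulocyte precursor genes 7 of 11 (7) and 1.47 (exact permutation adjusted p = 0.0244), and complement genes 7 of 13 higher and 1 lower (7 and 1) and 1.20 (exact permutation adjusted p = 0.0373).

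Several of the largest increases were of genes near 0 in PBS, and CTX140 1 had far higher values than the other CTX140 libraries for most of them. Mucl1 had 0 counts in PBS and was at least 71.3-fold higher at CTX140, with 11.0 of its CPM in CTX140 1 and at most 2.70 CPM in the others. Ratios of counts were 298 for Reg3g (95% counting interval 82.3 to 2467), 327 for Dmbt1 (58.3 to 12932) and 78.2 for the progesterone receptor gene Pgr (21.4 to 650). Reg3g was at 4.49 CPM or more in all 5 CTX140 libraries, whereas Dmbt1 was at 17.0 CPM and Pgr at 8.93 CPM in CTX140 1 and at most 3.37 and 1.07 CPM in the others. Upk3a, Thrsp and the chemokine gene Ccl17 had mean values of 10.3 ± 11.7, 35.8 ± 49.2 and 32.9 ± 43.8 CPM at CTX140, spreads as wide as the means; Upk3a was at 4.11 CPM or more in each library. Without CTX140 1 the log2 fold changes of Thrsp and Ccl17 were 5.60 and 4.94 in place of 6.88 and 6.20. Both genes fell step by step over CTX140 1 to 5, Thrsp from 120 to 37.1, 17.3, 3.76 and 0.749 CPM. Ccl17 went from 109 to 26.6, 18.2, 5.60 and 4.55 CPM. Scores on the first principal component had the same order, from 83.9 in CTX140 1 to 10.6 in CTX140 5. Among lower genes, the bone matrix gene Ibsp went from 32.0 ± 24.3 to 5.62 ± 3.32 CPM and the fractalkine receptor gene Cx3cr1, a marker of some macrophages, from 22.3 ± 8.97 to 4.78 ± 3.15 CPM (log2 fold changes -2.52 ± 0.44 and -2.22 ± 0.45). Prok2, Plag1, Npnt and Nptx1 had log2 fold changes of -2.00, -1.97, -1.79 and -1.75.

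**Figure D1:**
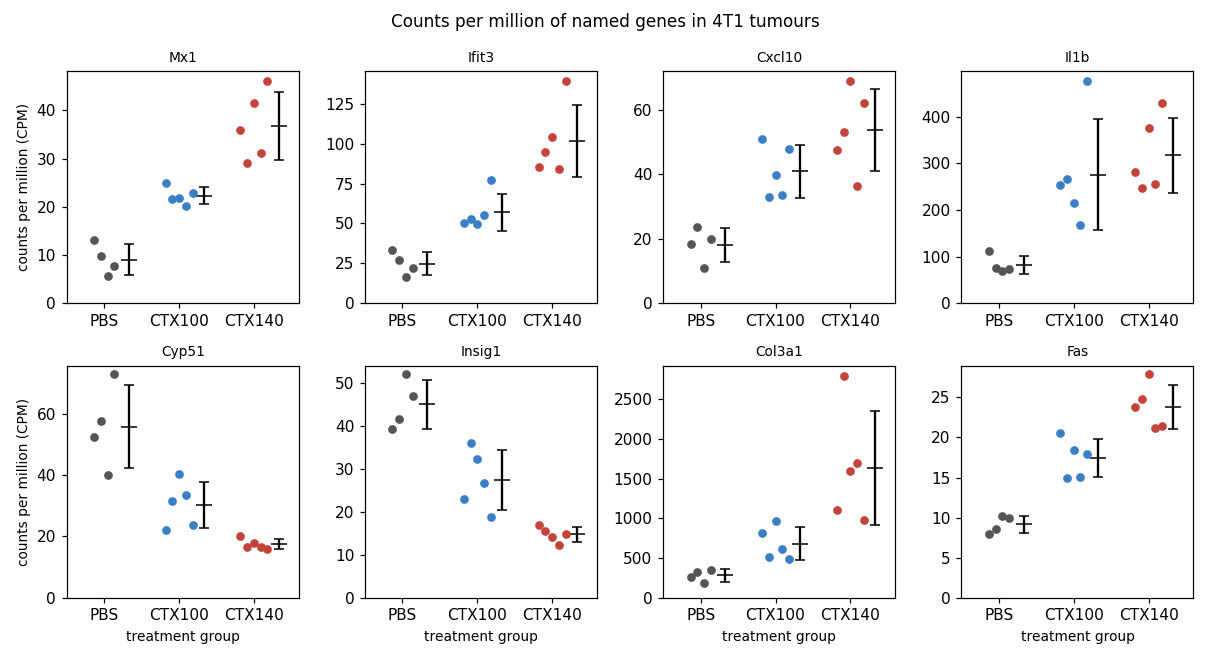
CPM (vertical axis) of 8 genes in PBS (n = 4), CTX100 (n = 5) and CTX140 (n = 5) tumours. Dots are libraries and bars are the mean ± SD. Mean Mx1 was 9.03, 22.3 and 36.8 CPM and mean Insig1 45.0, 27.3 and 14.7 CPM in that order.

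Camera called 19 lists at CTX140, 18 higher and 1 lower, and the permutation test of levels called 17. The lists called by both and not given above were pericytes (5 of 10 members higher; level 0.94 higher, exact permutation adjusted p = 0.0373), carcinoma epithelium (6 of 13; 1.32), skin (3 of 5; 2.13) and oxidant and drug detoxification (6 of 20; 0.63), with an exact permutation adjusted p of 0.0244 for the last 3. Levels alone passed for nerve (1 of 5; 1.35) and for TGF-beta and EMT genes (5 of 18 higher, 2 lower; 0.31), each with an exact permutation adjusted p of 0.0244. On log2(FPKM + 1) the difference of TGF-beta and EMT genes was 0.04 (exact permutation adjusted p = 0.635), and pericytes and detoxification lost their calls (exact permutation adjusted p = 0.0560 for each). Camera alone called T cells (4 of 13 members higher, 11 adjusted over the list alone), cytotoxic cells (6 of 13; 8), blood endothelium (1 of 13; 0) and checkpoint genes (6 of 14; 6), with adjusted p of 0.650, 0.427, 0.661 and 0.587 with an estimated correlation. The level of T cells was 3.22 ± 1.54 against 2.07 ± 0.66 (exact permutation adjusted p = 0.295), and camera lost that call without CTX140 1 (adjusted p = 0.0722). Camera also lost blood endothelium without PBS 2, PBS 4, CTX140 1 or CTX140 2, checkpoint genes without PBS 2, CTX140 1 or CTX140 2, and detoxification without PBS 4 (highest adjusted p = 0.171, 0.116 and 0.0533). The median, mean and test differed in sign in 1 list. With an estimated correlation camera called 0 of 40 lists (smallest adjusted p = 0.113 with an estimated correlation; raw p under 0.05 in 7), and fry called 18.

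The count of 3268 genes was 1975 without PBS 3 and 1992 without PBS 4, 1878 with only these groups fitted and 1299 at a log2 change of at least 1, and among the 32 entries taken by the naming rule Thrsp lost its call without PBS 4 and Prok2 without PBS 3. With the fibroblast level of a library as a covariate edgeR called 13 genes, but 85.7% of the variance of that level lies between the groups, so the covariate and the group overlap.

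The comparison of CTX140 with CTX100 tests the difference between the doses itself. The level of p53 targets was higher at 140 mg/kg and the levels of cholesterol synthesis and mitosis genes were lower, while fibroblast and complement genes had some members called higher without their levels passing. Of 15360 genes, 192 were called, 119 higher and 73 lower, and 3430 had a raw edgeR p under 0.05. Insig1 went from 27.3 ± 6.95 CPM at CTX100 (SD, n = 5) to 14.7 ± 1.77 CPM at CTX140 (n = 5), a log2 fold change of -0.89 ± 0.16 (adjusted p = 0.0260). Idi1 fell by 1.32 ± 0.26 on the log2 scale (adjusted p = 0.0294). The cholesterol list had 7 of 16 members called lower (12 adjusted over the list alone), with a level difference of -0.59 (exact permutation adjusted p = 0.0397).

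Mitotic genes were lower at CTX140 than at CTX100. Cenpf fell by 0.67 ± 0.13 on the log2 scale (adjusted p = 0.0284) and Bub1b by 0.59 ± 0.12 (adjusted p = 0.0358). The mitosis list had 3 of 21 members called lower (16 adjusted over the list alone), and its level was 6.31 ± 0.23 at CTX140 against 6.74 ± 0.09 at CTX100 (exact permutation adjusted p = 0.0397). The repair list had 1 of 18 called lower, Ercc1 at -0.51 ± 0.11 (adjusted p = 0.0384), with 1 adjusted over the list alone and a level difference of -0.21 (exact permutation adjusted p = 0.0397). Other lower genes were the semaphorin gene Sema4c (-1.03 ± 0.18), the developmental regulator Eya1 (-0.99 ± 0.19) and the linker histone gene H1f0 (-0.98 ± 0.18).

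Eda2r rose from 0.815 ± 0.215 CPM at CTX100 to 3.20 ± 1.39 CPM at CTX140 (log2 fold change 1.96 ± 0.41, adjusted p = 0.0347); it was the 1 member of the p53 list called of 20 (9 adjusted over the list alone), and the level of that list was 0.44 higher (exact permutation adjusted p = 0.0397). Interferon and inflammatory genes Ifit2, Ifit3, Ccl4 and Tnf rose by 0.72 ± 0.16, 0.83 ± 0.19, 1.15 ± 0.21 and 1.43 ± 0.32. The type I interferon list had 2 of 21 called higher (14 adjusted over the list alone) and the inflammatory list 2 of 23 (8 adjusted over the list alone). Camera called both (adjusted p = 5.82e-08 and 0.000140, but 0.342 for each with an estimated correlation), and their level differences of 0.49 and 0.50 did not pass (exact permutation adjusted p = 0.0529 and 0.123). Fap and Mfap5, of fibroblasts, rose by 1.30 ± 0.24 and 1.02 ± 0.22, Col14a1 by 1.45 ± 0.31, and the complement gene C3 by 1.17 ± 0.27, while the complement gene Serping1 rose 2.84-fold. The complement list had 2 of 13 called higher (7 higher and 1 lower adjusted over the list alone), and its level, 0.73 higher, did not pass (exact permutation adjusted p = 0.0847). The fibroblast list had 5 of 14 called higher (13 adjusted over the list alone); its level, 1.12 higher, did not pass (exact permutation adjusted p = 0.0529). Pfkfb3, of glycolysis, rose by 0.55 ± 0.12, but the level of its list of hypoxia and glycolysis was lower on average at CTX140, without passing. That level ran from 7.12 to 8.07 at CTX140 and from 7.97 to 8.14 at CTX100. Ces1d, Dmbt1, Cldn10, Ccl17 and Ces2g, with at most 2.92 CPM on average at CTX100, had the highest fold changes, from 3.41 to 3.81 on the log2 scale. CTX140 1 had the highest value of each: without it Dmbt1 and Ccl17 had log2 fold changes of 2.43 and 2.24 and lost their calls, and Ces1d, Cldn10 and Ces2g did not enter the test; the carboxylesterase genes Ces1d and Ces2g belong to families of near-copies.

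**Figure D2:**
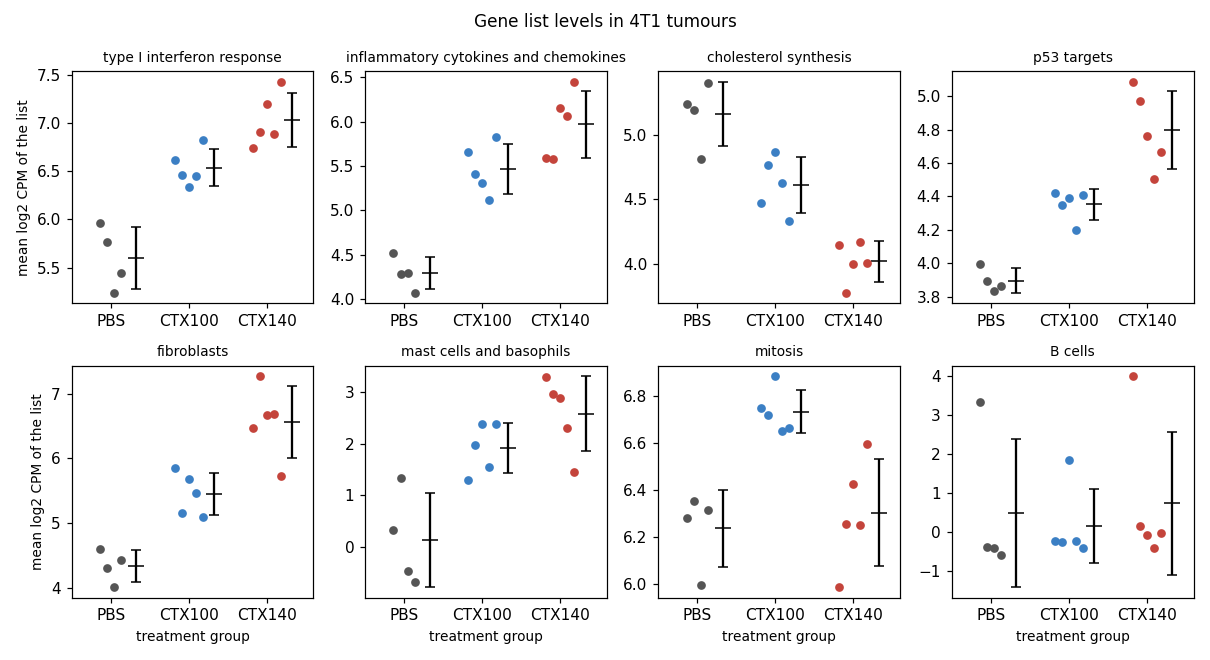
Level of 8 gene lists (vertical axis, mean log2 CPM of the list's tested members) in each PBS, CTX100 and CTX140 library. Dots are libraries and bars are the mean ± SD (n = 4, 5 and 5). The type I interferon level was 5.60, 6.54 and 7.03 and the mitosis level 6.24, 6.74 and 6.31 in that order.

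Camera called 27 lists between the doses, 22 higher and 5 lower, and the permutation test of levels called 8. In each of these 8 lists, the levels of the CTX140 libraries did not overlap those of the CTX100 libraries (exact permutation p = 0.00794, the smallest possible). With 1 library left out, 0 to 9 levels passed the adjustment, although the groups still did not overlap in these 8 lists. The others called by level were immature neutrophils (0.81 higher, 0 of 11 members called, 4 adjusted over the list alone), skin (1.26 higher, 0 of 5; 2), TGF-beta and EMT genes (0.15 higher, 0 of 18; 0) and oxidant and drug detoxification (0.40 higher, 1 of 20; 3), each with an exact permutation adjusted p of 0.0397. Adipocytes were 1.57 higher and T cells 1.13 higher without passing (exact permutation adjusted p = 0.0847 and 0.179). With an estimated correlation camera called 0 of 40 lists (smallest adjusted p = 0.262 with an estimated correlation; raw p under 0.05 in 6), and fry called 6. On log2(FPKM + 1) no level passed (smallest exact permutation adjusted p = 0.0635), and the difference of TGF-beta and EMT genes was 0.00118 (exact permutation adjusted p = 0.992).

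All 26 entries that the naming rule took for this comparison lost their call when some single library was left out. The number of genes called was 0 without CTX100 2, 3 or 4 or CTX140 3 (raw edgeR p under 0.05 for 2659 to 3089 genes), 1 without CTX100 1 or CTX140 2, 52 without CTX140 1, 162 without CTX100 5, 528 without CTX140 4 and 1007 without CTX140 5, against 1284 by DESeq2 with all libraries, 111 and 46 by limma on log2(FPKM + 1) and log2(FPKM + 0.1), 98 at a log2 change of at least 1, 12 without PBS 1, CTX100 3 and CTX140 1 together, and 2 with the fibroblast covariate.

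Both doses together were compared with PBS, and 2027 genes were called, 1014 higher and 1013 lower. The type I interferon list had 20 of 21 members called higher (20 adjusted over the list alone) and the cholesterol list 13 of 16 lower (15 adjusted over the list alone), with level differences of 1.18 and -0.85 (exact permutation adjusted p = 0.00999 for each). The DNA replication list had 8 of 21 called higher (11 adjusted over the list alone) and a level 0.28 higher (exact permutation adjusted p = 0.0447). Camera called 20 lists and the permutation test of levels 18. With an estimated correlation camera called 0 (smallest adjusted p = 0.108 with an estimated correlation; raw p under 0.05 in 8), fry called 17, and the median, mean and test differed in sign in 2 lists. The count of genes was 768 without PBS 3, 821 without PBS 4, 647 at a log2 change of at least 1 (569 higher and 78 lower) and 23 with the fibroblast covariate.

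Genes called at both doses were 160 higher and 59 lower, 219 in all, and none was called in opposite directions. Of the 245 genes called at CTX100, 243 had the same sign at CTX140 (99.2%) and 174 a larger change there; of the 3268 called at CTX140, 3168 had the same sign at CTX100 (96.9%); these genes were selected by their calls and share the PBS libraries. Over all genes, 76.1% had the same sign, against a mean of 68.9% and a highest of 69.7% in the simulated unchanged groups. These simulations drew each gene independently, so their ranges do not allow for genes that vary together. The PBS libraries were simulated too, so these values do not carry traits of the real PBS libraries. Independent lists of these sizes would share 20.5 higher and 6.18 lower genes. Unchanged groups compared with the same simulated PBS libraries shared 0. They had too few calls to share, so that value does not measure the part of shared controls in the overlap. Across genes, which are not independent replicates, the fold changes of the doses had a Pearson r of 0.719 (simulated mean 0.564, highest 0.629) and a covariance of 0.290 against 0.0621 simulated, a difference of 0.228. With a different pair of the PBS libraries used for each dose, the mean of 6 assignments was 39.3 shared genes (0 to 213), r was 0.468 and the covariance 0.250. In these fits 64.9% of all genes had the same sign on average (61.1 to 67.3%). The 219 shared genes became 616 without PBS 2, 17 without PBS 3, 27 without PBS 4, 91, 75, 49, 67 and 49 without CTX100 1 to 5, 337 without CTX140 1, 114 without CTX140 3 and 699 by DESeq2.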

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

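Of the tests below, the leaving out of the libraries with high B cell levels and the choice of the lymph node genes followed from seeing the B cell levels. Within each group of 4 or 5 libraries, a value was picked out when the gap between the highest or lowest library and its nearest neighbour took a larger part of the group's range than Dixon's 95% limit allows. Of 338 groups of values, 34 had such a library (10.1%), where chance gives about 1 in 20 for continuous values: 24 of 206 for named genes and 10 of 132 for lists and library measures. Where the other libraries are at 0 any single count is picked out, and the named genes had been chosen for large fold changes, so the excess among them is partly set in advance. CTX140 1 had 9 of them, PBS 1 had 6, CTX100 3 had 5 and PBS 3 had 3.

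Among lists and measures, the B cell level was high in PBS 1 (3.35), CTX100 3 (1.85) and CTX140 1 (3.99), and the plasma cell level in PBS 1 (6.09). Haemoglobin transcripts took 0.0284% of counts in CTX140 5. The level of immature neutrophils was high in CTX140 2 (2.80), that of dendritic cells low in CTX100 4 (1.64), that of TGF-beta and EMT genes high in PBS 3 (4.55) and CTX140 2 (4.98), and that of ribosomal proteins low in CTX140 1 (10.1).

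Among named genes, CTX140 1 was highest in its group for Mucl1 (11.0 CPM), Dmbt1 (17.0 CPM), Upk3a (31.3 CPM), Ccl17 (109 CPM), Pgr (8.93 CPM), Cldn10 (7.37 CPM) and Idi1 (5.51 CPM). In other CTX140 libraries, Ibsp was high in CTX140 4 (11.3 CPM) and Il1a in CTX140 5 (19.9 CPM). In CTX100, Spp1 (2462 CPM) and Adamtsl3 (5.11 CPM) were low and Upk3a (4.56 CPM) and Thrsp (12.0 CPM) high in CTX100 3, Mucl1 was high in CTX100 2 (1.43 CPM) and Ifit3 in CTX100 5 (77.2 CPM). In PBS, Dmbt1 (0.0603 CPM), Upk3a (0.241 CPM), Thrsp (1.02 CPM) and Rrm2 (73.1 CPM) were high in PBS 1, Pgr (0.137 CPM) and Ces2g (0.410 CPM) in PBS 2, Reg3g (0.140 CPM) and Itga8 (3.84 CPM) in PBS 3 and Ido1 (6.32 CPM) in PBS 4. Several of these PBS values are 1 or 2 counts.

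The B cell and plasma cell levels of PBS 1 and CTX140 1 may come from lymph node tissue taken with the tumour. A list of 6 genes of lymph node stroma and vessels, 4 of them among the tested genes, was lowest at 1.16 in these libraries (3.07 in CTX140 1) and highest at 0.226 among the other 12, a gap of 0.938. Its most abundant gene, Glycam1, stood at 109 CPM in PBS 1 and 391 CPM in CTX140 1, and is also a gene of milk-producing mammary epithelium; Ccl21a is also in the list of lymphatic endothelium. Not every gene set PBS 1 apart: Cxcl13 was at 8.40 CPM there and 10.5 CPM in CTX140 2. Madcam1 was at 0.487 CPM in PBS 1 and 1.32 CPM in CTX140 5. CTX100 3, with a high B cell level, stood at 0.0526 for this list. Lymphoid tissue formed inside the tumour has the same genes and stays open, and no biological explanation for these libraries was tested. Without PBS 1, CTX100 3 and CTX140 1, 12 genes were called between the doses, against 192.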

How the results depend on the processing

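RLE and upper quartile factors, the filter of 1 CPM in 4 libraries, no filter, and leaving out the lists of blood, muscle, fat, skin and plasma cells kept every count of genes and lists they were run for within 1.5 times; of entries taken by the naming rule, 87 of 87 kept their call with RLE factors, 86 of 87 with upper quartile factors and 70 of 87 without a filter. Where a count moved, the cause was not tested unless stated. For CTX100 against PBS, CTX140 against PBS, CTX140 against CTX100 and both doses against PBS, requiring a log2 change of at least 1 left 117, 1299, 98 and 647 genes (108 and 9, 1117 and 182, 95 and 3, and 569 and 78 higher and lower). Fitting only the groups compared gave 529 genes for CTX100 and 1878 for CTX140, each against PBS. DESeq2 called 847 genes for CTX100 against PBS and 1284 between the doses, and 699 genes shared by the doses. Limma on log2(FPKM + 1) called 155 for CTX100 against PBS and 111 between the doses, and on log2(FPKM + 0.1) 46 between the doses, of which 45.7% were higher. No list level passed between the doses on log2(FPKM + 1), 0 of 40. Camera with an estimated correlation called 0 lists in each contrast (raw p under 0.05 in 9, 7, 6 and 8 lists), and fry called 10 lists for CTX100 against PBS and 6 between the doses. With a different pair of the PBS libraries used for each dose, 39.3 genes were shared on average; these fits hold fewer controls.

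With the replicate number as a block, 82 genes were called for CTX100 against PBS (78 higher, 4 lower) and 322 between the doses (241 higher, 81 lower); for both doses against PBS the split was 895 higher and 571 lower, against 1014 and 1013 without the block. Residuals of the 13 same-numbered pairs had correlations from -0.193 to 0.431, median 0.0712, and 6 were over 0.1. The 52 other pairs ran from -0.361 to 0.333, median -0.0135, with 15 over 0.1. Of the 14 libraries, 4 correlated best with their own number. These values do not settle whether the numbers mark a shared structure of the libraries, so the results with the block stay open as well.

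Leaving out 1 library at a time gave 17 to 686 genes for CTX100 against PBS, 1975 to 3894 for CTX140 against PBS, 0 to 1007 between the doses and 768 to 2796 for both doses against PBS (edgeR; 192 genes between the doses with all libraries, 1284 by DESeq2). Lists called by camera ranged over 15 to 20, 18 to 23, 21 to 28 and 18 to 24, and genes shared by the doses over 17 to 616. List levels passed in 0 to 0, 0 to 16, 0 to 9 and 9 to 18 lists. For a pair of groups, fewer libraries make the exact test coarse: its smallest p was 0.00794 to 0.0286. Many lists had to reach that p together to pass the adjustment over 40 lists, so a drop to 0 says little about stability. For both doses against PBS the smallest p was 0.00140 to 0.00350, and the counts were not limited in this way. The 8 levels called between the doses separate the groups without overlap, which leaving out a library cannot undo. With unequal groups such a separation need not give the smallest p. Of calls for entries taken by the naming rule, 26 of 29, 2 of 32 and 26 of 26 were lost without some library for CTX100 against PBS, CTX140 against PBS and CTX140 against CTX100. Of lists called by camera, 1 of 16, 4 of 19 and 9 of 27 were so lost, and 6 of 20 for both doses against PBS.

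Alternatives chosen after seeing the data were the fibroblast level as a covariate and leaving out PBS 1, CTX100 3 and CTX140 1. Without these libraries 12 genes were called between the doses. With the covariate 20, 13, 2 and 23 genes were called; 85.7% of the variance of that level lies between groups, so the covariate takes up the group difference by construction. It took the log2 fold changes of Mfap5 and Fbn1 for CTX140 against PBS to about 0 (-0.00307 and -0.00591, adjusted p = 0.998 and 0.997), and reversed the blood endothelium (-1.49) and matrix (-0.361) lists for CTX140 against PBS, and the macrophage (-0.486), blood endothelium (-0.495) and matrix (-0.255) lists between the doses.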

Other observations

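Chosen only after the result was seen were the test of the fibroblast level against the macrophage level, both tests of the carcinoma share for the mitosis list, and the test of gene families.

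Other splits of the same libraries, 100 per contrast, were refitted. For genes, other splits seldom called as many, which argues against chance without excluding it. Of the 100, 2 splits, the real one included, reached the 245 genes of CTX100 against PBS (highest other 449). Only the real one reached the 3268 of CTX140 against PBS (highest other 2054) and the 192 of CTX140 against CTX100 (highest other 2). Likewise only the real one reached the 2027 of both doses against PBS (highest other 965). The split with 449 genes set PBS 2 with CTX100 3, 4 and 5 against the rest, which points to a structure of the libraries beside the dose. For CTX140 against CTX100, camera called 27 lists. Of the 100 splits, 2 reached that number, the real one included (highest other 28, median of the others 16). Such a count was rare among the splits, which argues against chance for the count but not for each list. None of the 27 was called by camera with an estimated correlation (smallest adjusted p = 0.262) and 9 were lost without some library. For the lists of the other contrasts chance stays open. Splits as large numbered 31 for CTX100 against PBS (16 lists, highest other 21) and 35 for CTX140 against PBS (19, highest other 25). For both doses against PBS they numbered 14 (20 lists, highest other 27).

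The fibroblast list was higher at CTX140 than in PBS, which may reflect the make-up of the pieces rather than a response of fibroblasts. A lower carcinoma share would raise the markers of every other cell type alike. The fibroblast level minus the macrophage level was 2.10 higher at CTX140 (exact permutation p = 0.00794, the smallest possible). The macrophage level itself differed by only 0.13, so this difference was nearly set by the fibroblast rise. Pericyte and mast cell levels were higher too, and so was that of carcinoma epithelium, so these values do not decide on this explanation. Surrounding fat would raise fibroblast with adipocyte genes. After removing the slope on the adipocyte level within groups (0.166), the difference was 1.72 (2.23 before), above the largest SD within a group (exact permutation p = 0.00794). The adipocyte levels of PBS (at most 1.25) and CTX140 (at least 2.45) did not overlap, so the slope was carried from within the groups to between them. So shallow a slope could remove only a small part of the difference, and this test does not decide on fat. Surrounding fat, a lower carcinoma share, other skin or mammary tissue and a response to the drug stay open.

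The mitosis list was lower at CTX140 than at CTX100, and a lower share of carcinoma cells is a candidate explanation that these libraries leave open. In the test chosen first, the level of the 13 carcinoma epithelium genes was 0.69 higher at CTX140 (exact permutation p = 0.0159), which taken alone goes against a lower share. That level weighs every gene alike, few of the genes are abundant, and it was highest in CTX140 1 (5.33). It may therefore not follow the share of carcinoma cells. The second test was added after that result and its gene values were seen, with a limit of 100 CPM in PBS that kept only Krt8 and Krt18: their level differed by -0.31 (exact permutation p = 0.00794), and the mitosis level minus theirs by -0.12 (exact permutation p = 0.476), which goes with a lower share but could hardly have come out otherwise. As the measures go opposite ways, the share of carcinoma cells and a slower division of these cells cannot be told apart. Scaling between libraries is argued against by the mitosis level minus the ribosomal protein level, which differed by -0.47 (exact permutation p = 0.0238).

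Genes were also grouped by the stem of their symbol into 320 families, and each was tested for an excess of called genes by Fisher's exact test, against 12369 genes and adjusted over families and directions. At CTX140 against PBS the higher genes held 6 of 6 Ifit genes and 10 of 16 Ccl genes (adjusted p = 0.000408 for each), 16 of 35 Col genes (adjusted p = 0.000337), 10 of 16 Ifi genes (adjusted p = 0.000408) and 7 of 10 Cxcl genes (adjusted p = 0.00331). Also past the threshold were 6 of 9 Tnfsf genes (adjusted p = 0.0125), 6 of 10 Car genes, 5 of 7 Apol genes and 5 of 7 Slfn genes (adjusted p = 0.0218 for each of the last named 3). Of all 12369 genes, 1448 were called higher and 1379 lower in this contrast. The lower genes held 6 of 9 Hoxa genes, with a median log2 fold change of -1.04. They also held 60 of 337 Zfp genes, with a median of -0.23 (adjusted p = 0.0125 for Hoxa and for Zfp). At CTX100 against PBS, 5 of 6 Ifit genes (adjusted p = 1.21e-06) and 4 of 16 Ccl genes (adjusted p = 0.0132) were among the higher ones. Members of a family are not independent of one another, and near-copies may share reads.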
